A study of Homo sapiens with 6 samples.

How the data were processed

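Gene expression was measured in PC-3 cells, an established human prostate cancer line, on 6 two-colour Agilent expression arrays of design 28004. Per the labels, cell pools carrying a lentiviral hairpin against ETV4 (shETV4) or a non-target hairpin (shNTC) were kept for 24 h in 20% oxygen or in 0.2% oxygen. Each oxygen level has 3 arrays, from cultures grown independently. Each array compared both pools at 1 oxygen level. The 12 channels form 4 RNA groups of 3 channels. On all 6 arrays the shNTC RNA was read as Cy5 and the shETV4 RNA as Cy3. A dye effect specific to a probe therefore adds to its shETV4 effect. It cancels from the difference between oxygen levels if it is equal on all arrays, and the oxygen comparisons stay within 1 dye. All 6 arrays were on 1 slide and were read in 1 scan, so neither separates the groups. By the position codes in the file headers, the 20% oxygen arrays lay at 1_1, 1_3 and 2_2 and the 0.2% oxygen arrays at 1_2, 2_1 and 2_3.

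The deposited scanner files hold spot and local background intensity as medians for each dye, made with Agilent Feature Extraction 10.7.3.1 per the file headers. They also hold background-subtracted and dye-normalised processed intensity. The authors' value table holds the log10 ratio of processed Cy5 over processed Cy3, shNTC over shETV4. It equals the log ratio column of the deposited scanner files with a largest difference of 0, and the median of each of its 6 columns is 0. The submitters' notes name Feature Extraction and limma without saying what each was used for. The deposited files hold no mean spot signals, so medians were used in their place.

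Signals were processed in R 4.3.3 with limma version 3.58.1, and files were read with the data.table package, version 1.17.8. Background was corrected by normexp with an offset of 50. Of 62976 spots, 4259 control spots were left out after that step. The log2 ratio of Cy3 over Cy5, shETV4 over shNTC, was normalised by loess within each array. Spots marked by the scanner software as non-uniform or as population outliers were left out when spots of a probe were averaged, which removed 31 probes. A probe was kept if it was well above background on all 3 arrays of at least 1 of the 4 RNA groups. This kept 18580 of 42405 probes. Probes were given gene symbols through their transcript accessions and the current RefSeq table. Of all probes, 25505 (60.1%) matched 1 symbol and 16900 matched none, and those without a symbol entered the fit but no gene count. A gene was represented by its kept probe of highest mean intensity, which gave 12054 genes tested, 2376 of them with several kept probes. No positions are given, since only symbols were available. No spot was saturated.

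The shETV4 effect at each oxygen level, its mean over both levels and its difference between levels came from 1 limma fit (lmFit and eBayes) to the log2 ratios of all 6 arrays, with a mean per oxygen level. The fit has 4 residual degrees of freedom. The effect at 1 level therefore borrows its spread from both. The effect of 0.2% against 20% oxygen within each pool came from limma's separate-channel fit (lmscFit) after Aquantile normalisation between arrays. Its estimated correlation within spots was 0.43. A SE marked as that of a fit is its moderated one, and not the scatter of the arrays at 1 oxygen level. All p values are two-sided and were adjusted by Benjamini-Hochberg over the 12054 genes of a comparison. The threshold was an adjusted p of 0.05, and the words higher, lower, rose and fell are used of genes below it. There are 6 such comparisons.

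Before the data were examined, 16 gene lists, the comparisons, the rule for named genes and most alternatives were fixed. The lists cover targets of the hypoxia-inducible factors (HIF) in glucose metabolism, other HIF targets, ETS factors, reported targets of the PEA3 subfamily to which ETV4 belongs, RAS-ERK output, cell cycle, mesenchymal genes, epithelial genes, the unfolded protein and amino acid response, interferon response, cholesterol synthesis, the respiratory chain, NF-kB and inflammatory genes, prostate luminal and neuroendocrine markers, markers of other cell types, and ribosomal proteins. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 (cameraPR for the oxygen comparisons), adjusted over the 16 lists of a comparison. Each was tested again with the correlation estimated from the residuals. The fry test asks whether a list moves, on balance, one way, and does not compare it with other genes. The named genes are ETV4 and its paralogs, per comparison the 10 largest rises and 10 largest falls among genes past the threshold whose arrays all moved the same way (for the oxygen comparisons, whose groups do not overlap), the 4 members of smallest p in the direction of each list that passed, and the 4 members of smallest p of both HIF lists. Where no gene passed, the 5 of smallest p in each direction were named as not passing. Some genes that this rule takes are not reported here.

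To ask whether genes raised by low oxygen in shNTC cells responded differently in shETV4 cells, genes at least 2-fold higher at 0.2% oxygen were chosen on 2 replicate numbers. Their difference in log2 ratio was then measured in the number left out, in 3 rotations. An exact two-sided sign-flip permutation test over the rotations cannot go below p = 0.25.

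Whether replicate numbers pair the arrays was checked by correlating deviations from the group means across oxygen levels. With equal numbers the correlations across probes were 0.30, 0.34 and 0.39 for the log2 ratios and 0.31, 0.56 and 0.62 for the shNTC channels. For the shETV4 channels they were -0.53, -0.09 and -0.54. Fits with the replicate number as a block were run as an alternative.

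Other alternatives changed the background correction, the filter, the probe standing for a gene, the features adjusted over, the normalisation within and between arrays, the source of the values and the samples in the fit, or left out 1 array. A setting that keeps only 1 of the arrays at 0.2% oxygen was added after the data were seen. Other alternatives added then were a left-out array for the list tests, the held-out measure and the ETV4 ratio, and every processing choice for the list tests. A block for the slide was not possible with 1 slide, and no other ETV4 probe was on the array.

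The fits were tested on simulated normalised values with the spread of the 6 arrays and 12054 genes. Of these, 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. Values were drawn independently with 1 spread per probe at both oxygen levels, so background correction, loess and unequal arrays were not covered. Recovery at 0.2% oxygen may therefore be overstated. Of genes changed by 2, 75.8% were recovered in the shETV4 comparison at either oxygen level, 97.0% on the mean of both levels, 50% in the difference between levels, and 87.9% and 84.9% in the oxygen comparisons of shNTC and shETV4 cells. Of genes changed by 1, 28.4% and 23.9% were recovered at 20% and 0.2% oxygen and 0% in the difference. The number of arrays limits the precision of every value.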

Results

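The data are 6 two-colour arrays of PC-3 RNA, 3 at 20% oxygen and 3 at 0.2% oxygen, each setting shETV4 cells against shNTC cells. ETV4 is a transcription factor of the ETS family, and the labels cross its knock-down with low oxygen. In 11 of the 12 channels, between 46.0% and 55.8% of spots were well above background. The shNTC channel of the array labelled 0.2% oxygen replicate 1 had 24.4%, and its bright spots were 20.5-fold below the median of the Cy5 channels.

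ETV4 itself was lower in shETV4 cells at 20% oxygen and did not pass at 0.2% oxygen. At 20% oxygen its background-subtracted signal in the shNTC channels was 862, 838 and 87.8 units, and 112, 84.5 and 34.8 units in the shETV4 channels of the same arrays. The log2 ratio was -2.11 ± 1.00 (SD, 3 arrays, adjusted p = 0.0193). Neither ETV4 spot was above background in the shETV4 channels of 20% oxygen replicate 3 and of the array labelled 0.2% oxygen replicate 1, and 1 of 2 was on that labelled 0.2% oxygen replicate 2, so the size of the fall is uncertain. At 0.2% oxygen the shNTC channels read 29.5, 114 and 63 units and the shETV4 channels 38.5, 37.3 and 90.5 units. These units are not scaled for the brightness of a channel, and the 29.5 comes from the dim channel described above. Relative to the median of probes above background in all channels, shNTC ETV4 was 0.40, 0.08 and 0.05 at 0.2% oxygen. At 20% oxygen it was 0.43, 0.24 and 0.06. The log2 ratios at 0.2% oxygen were -0.84, -1.23 and -0.11, with a mean of -0.73 ± 0.56 (SD) that did not pass (adjusted p = 0.323). Over both levels the log2 ratio of ETV4 was -1.42 (adjusted p = 0.0148). Processed signals gave ETV4 ratios of -3.1 and -2.15 at 20% and 0.2% oxygen, and the authors' log ratios -3.16 and -2.19. Without the array of 20% oxygen replicate 1 or 2 the ratio at 20% oxygen no longer passed, at -1.72 (adjusted p = 0.15) and -1.95 (adjusted p = 0.156), nor did it with median centring, at -2.06 (adjusted p = 0.166). The array labelled 0.2% oxygen replicate 3 showed little difference in ETV4.

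**Figure D1:**
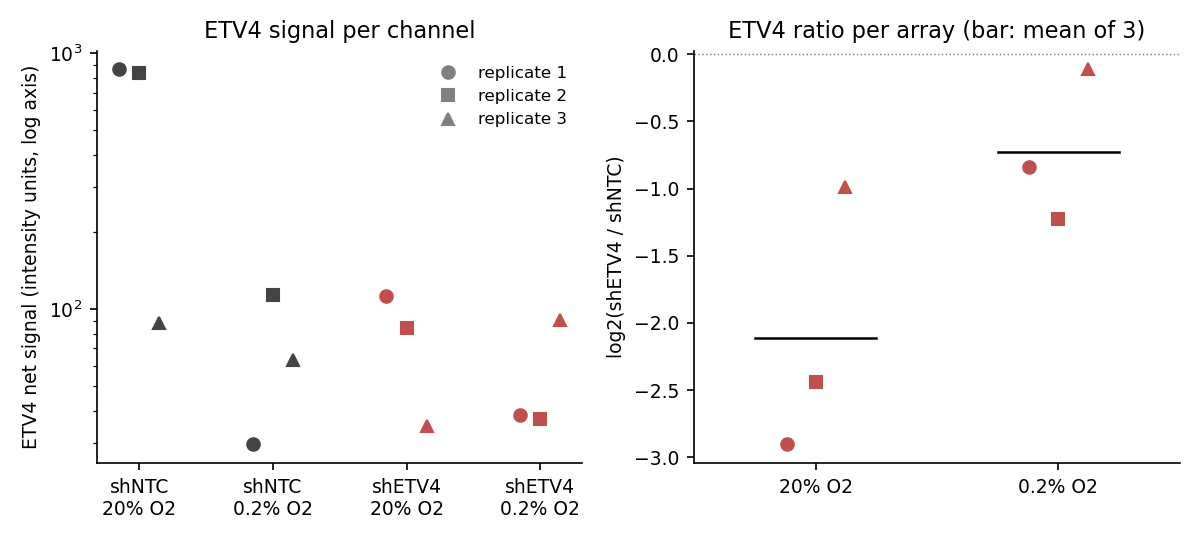
ETV4 in every channel. One panel gives the background-subtracted ETV4 signal of each channel in arbitrary units on a log axis, the other the log2 ratio of shETV4 over shNTC per array with bars at the mean of 3 arrays. The ratios at 20% oxygen lie at -2.90, -2.44 and -0.99, and those at 0.2% oxygen at -0.84, -1.23 and -0.11.

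The transcriptional response to low oxygen was seen in both pools. The median of 61 HIF targets, measured against the 20% oxygen channels of the same pool, was 1.47, 1.65 and 1.82 higher on the log2 scale in the shETV4 channels at 0.2% oxygen. In the shNTC channels it was 2.25 and 1.92 higher on the arrays labelled replicates 2 and 3. On the array labelled replicate 1, the dim channel, it was 0.70 higher.

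**Figure D2:**
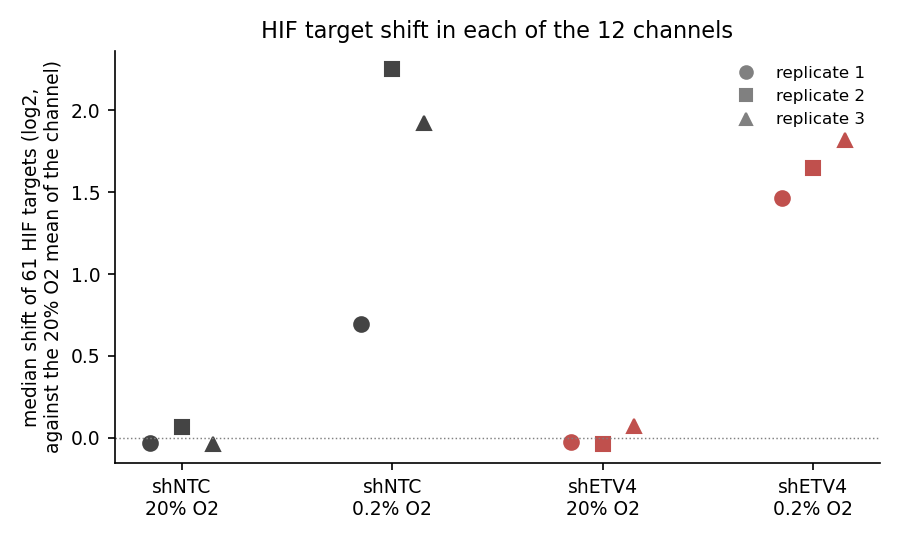
Median log2 shift of 61 HIF targets in each of the 12 channels, against the mean of the 3 channels of the same pool at 20% oxygen. Each point is a channel. The shNTC channel labelled 0.2% oxygen replicate 1 sits at 0.70 and the other 5 channels at 0.2% oxygen between 1.47 and 2.25.

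The comparison of shETV4 with shNTC cells at 20% oxygen asked what the knock-down changed in normal culture. Of genes typical of epithelia 8 of 18 were lower in shETV4 cells, and the call of their list was lost with an estimated correlation. The 8 included the serine protease ST14 (5.30-fold), the tight junction protein CLDN7 (7.27-fold), the splicing regulator ESRP1 (5.14-fold) and the cadherin CDH3 (3.79-fold). The intermediate filament gene VIM, a common mesenchymal marker, was 11-fold higher (log2 3.46 ± 0.35, SE, 3 arrays). The largest falls were in LCN2, which binds siderophores and was 16.3-fold lower, and in NNMT, the nicotinamide N-methyltransferase, which was 15.7-fold lower. ATP2C2, TGFBI, PRSS8, S100A14, HOXB9, BSPRY and LAD1 were 10.5-fold to 14.9-fold lower. Among the rises were FEZ1 (11.1-fold), the thyroid hormone deiodinase DIO3 (10.9-fold), the claudin CLDN14 (10.5-fold) and FGFBP1, which binds fibroblast growth factors (10.4-fold). NPTX1 was at least 8.78-fold higher, and REEP2, ZNF569, PDGFRA and EPB41L3 were 7.73-fold to 9.38-fold higher. ETV1, a paralog of ETV4, was 2.64-fold higher (adjusted p = 0.0125). ETV5 was not among the genes tested.

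Of 18 epithelial genes measured at 20% oxygen, 8 fell, none rose and 10 did not pass, and adjusted over the list alone 10 fell. Their median log2 ratio was -0.85 (camera adjusted p = 2.24e-07, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.00365). The other 15 lists did not pass at 20% oxygen, though the NF-kB list did with median centring (adjusted p = 0.0231) and the mesenchymal list in the fit to the 3 arrays alone (adjusted p = 0.0428). Of 15 mesenchymal genes 5 rose, 1 fell and 9 did not pass, and adjusted over the list alone 5 rose and 2 fell (median 0.13, adjusted p = 0.527). VIM and TGFBI moved in opposite directions. The other 4 that rose, CDH2 (log2 2.38), ZEB1 (2.30), AXL (1.07) and CCN2 (0.58), are outside the rule for named genes and were chosen after their values were seen, as were the other single list members named for a small count below. Of 17 reported PEA3 targets VIM rose, MMP9 (log2 -1.25) and PTGS2 (-1.90) fell and 14 did not pass, and adjusted over the list alone 1 rose and 3 fell (median -0.19, adjusted p = 0.367). Of 13 ETS factors, ETV1 rose and 12 did not pass, with the same count adjusted over the list alone (median 0.19, adjusted p = 0.545). None of 19 RAS-ERK genes passed, and adjusted over the list alone 1 rose and 1 fell (median 0.08, adjusted p = 0.76). Of 22 HIF targets in glucose metabolism, PFKFB3 (2.71-fold) and ENO2 (2.20-fold) rose and 20 did not pass, with the same count adjusted over the list alone (median 0.10, adjusted p = 0.529). PFKP (log2 0.57) and GBE1 (0.86) were among those. Of 39 other HIF targets TMEM45A rose 4.49-fold, BHLHE41 was 3.29-fold lower and 37 did not pass, again with the same count adjusted over the list alone (median 0.07, adjusted p = 0.741). IGFBP3 (log2 1.71) and KDM3A (0.92) did not pass. Of 20 NF-kB and inflammatory genes IL1B (log2 1.94) and IRAK2 (1.17) rose, IL6 (-2.10), CCL20 (-1.44), PTGS2 and TNFAIP2 (-1.81) fell and 14 did not pass, and adjusted over the list alone 3 rose and 4 fell (median -0.36, adjusted p = 0.314). Of 28 cell cycle genes CCNA2 (-0.69), AURKB (-1.05) and MCM4 (-1.60) fell, also adjusted over the list alone (median -0.10, adjusted p = 0.367). Of 8 prostate markers HOXB13 rose (log2 1.14) and FOLH1 fell (-1.48), also adjusted over the list alone (median -0.11, adjusted p = 0.677). Of 6 markers of other cell types PDGFRA rose and 5 did not pass, also adjusted over the list alone. The median of those 6 and their camera test were negative and their mean positive (median -0.22, mean 0.19, adjusted p = 0.545).

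In total 658 genes were higher and 454 lower in shETV4 cells at 20% oxygen, 1112 of 12054, and 346 and 286 of them differed at least 2-fold. Leaving out an array moved this count strongly. It was 41, 32 and 117 without the arrays of 20% oxygen replicates 1, 2 and 3, and 1686 and 3188 without those labelled 0.2% oxygen replicates 1 and 3. The fit to the 3 arrays at 20% oxygen alone gave 5101, the authors' log ratios 555, processed signals 588, the filter on all 12 channels 238 and median centring 15. The excess of higher genes was lost with that filter, which gave 101 higher and 137 lower, 42.4% higher in place of 59.2%. It was also lost without the arrays of 20% oxygen replicates 1, 2 and 3, with 16, 12 and 52 higher and 25, 20 and 65 lower.

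At 0.2% oxygen the question was what the knock-down changed in low oxygen. LCN2 was 13-fold lower (log2 -3.70 ± 0.20, SE, 3 arrays) and the calcium-binding S100A9 11.4-fold lower. FGFBP1 was 8.57-fold higher (log2 3.1 ± 0.29, SE of the same fit) and VIM 7.68-fold higher. S100A14, LAD1, PRSS8, BSPRY, MPZL2, NNMT and HOXB9 were 6.77-fold to 10.4-fold lower. The neurotensin receptor NTSR1, REEP2, the protease ADAMTS1, the retinol carrier RBP4, FEZ1, ANXA10, MRC2 and EPB41L3 were 4.62-fold to 7.12-fold higher. ETV1 had a log2 ratio of 0.75 and did not pass (adjusted p = 0.125).

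At 0.2% oxygen 7 lists passed camera at the preset correlation, and none held its call with an estimated one. Of 28 cell cycle genes 2 fell, none rose and 26 did not pass, while adjusted over the list alone 13 fell (median -0.62, adjusted p = 4.09e-11, adjusted p = 0.224 with an estimated correlation). The replicative helicase subunit MCM4 was 2.74-fold and the cyclin CCNA2 1.91-fold lower, and BIRC5 (log2 -0.96) and CCNB2 (-0.99) did not pass. Of 18 epithelial genes 4 fell and 14 did not pass, and adjusted over the list alone 2 rose and 10 fell (median -0.63, adjusted p = 1.22e-06, adjusted p = 0.208 with an estimated correlation). Those 4 were ST14 (4.05-fold), CLDN7 (4.22-fold), CDH3 (3.64-fold) and EPCAM (3.06-fold). Of 25 interferon response genes OASL rose 3.05-fold and 24 did not pass, and adjusted over the list alone 9 rose (median 0.42, adjusted p = 0.00217, adjusted p = 0.321 with an estimated correlation). IFI44L (log2 2.57), IFI44 (0.93) and IFIT1 (0.96) did not pass. None of 22 HIF targets in glucose metabolism passed, and adjusted over the list alone 4 rose (median 0.48, adjusted p = 0.00655, adjusted p = 0.574 with an estimated correlation). Its smallest p values belonged to GYS1 (log2 1.26), ENO2 (1.19), SLC16A3 (0.61) and PFKFB3 (1.10). On the array labelled replicate 1 the ratios rest on the dim shNTC channel. The median shift of 61 HIF targets was 0.70 there, against 1.47 in its shETV4 channel. On the arrays labelled replicates 2 and 3 it was 2.25 and 1.92 in shNTC and 1.65 and 1.82 in shETV4 channels. The higher ratios of the glucose list are therefore not clear of the doubted channel. None of 20 NF-kB and inflammatory genes passed, and adjusted over the list alone 2 rose and 5 fell (median -0.38, adjusted p = 0.00642, adjusted p = 0.321 with an estimated correlation). Examples were TNFAIP2 (log2 -1.0), PTGS2 (-1.88), CXCL1 (-1.61) and CXCL8 (-1.58). No gene of 24 of the respiratory chain passed, adjusted over the list alone either (median -0.22, adjusted p = 0.00934, adjusted p = 0.321 with an estimated correlation), with NDUFA9 at -0.63, COX6C at -0.54, ATP5F1A at -0.46 and NDUFB8 at -0.28. The same held for 28 ribosomal proteins (median -0.20, adjusted p = 0.000951, adjusted p = 0.321 with an estimated correlation), with RPS12 at -0.71, RPL6 at -0.54 and RPL35 at -0.45. Of 39 other HIF targets TMEM45A rose 3.51-fold, BHLHE41 was 2.68-fold lower and 37 did not pass, and adjusted over the list alone 2 rose and 1 fell. TFRC (log2 1.29) and PLOD1 (1.21) were among those that did not. The median and mean of these targets were 0.02 and 0.04, while the camera test pointed down (adjusted p = 0.888).

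Median centring in place of loess moved the median log2 ratio of all genes at 0.2% oxygen by 0.64. With it the medians of the cell cycle (0.18), epithelial (0.40), NF-kB (0.33), respiratory chain (0.81) and ribosomal (1.09) lists were positive. Camera, which compares a list with the other genes, still called the cell cycle (adjusted p = 0.000587), epithelial (adjusted p = 0.000587) and NF-kB (adjusted p = 0.011) lists lower. It lost the calls of the respiratory (adjusted p = 0.919) and ribosomal (adjusted p = 0.77) lists, and that of the glucose list (adjusted p = 0.354). The doubted arrays weighed on several lists. Without the array labelled 0.2% oxygen replicate 3 the interferon (adjusted p = 0.0782), NF-kB (adjusted p = 0.0697) and glucose (adjusted p = 0.508) lists did not pass. Without the one labelled replicate 1 the glucose (adjusted p = 0.15), respiratory (adjusted p = 0.311) and ribosomal (adjusted p = 0.15) lists did not pass, and the other HIF targets passed with a median of -0.46 (adjusted p = 8.95e-05). The filter on all 12 channels ended the interferon call (adjusted p = 0.0978) and the authors' log ratios the glucose (adjusted p = 0.0848) and ribosomal (adjusted p = 0.287) calls, the last also lost with processed signals (adjusted p = 0.23). In fry only the cell cycle (adjusted p = 0.0418) and epithelial (adjusted p = 0.00991) lists passed.

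In total 147 genes were higher and 75 lower in shETV4 cells at 0.2% oxygen, 222 of 12054, and 102 and 65 of them differed at least 2-fold. The count rests on the spread shared with the 20% oxygen arrays. A limma fit to the 3 arrays at 0.2% oxygen alone called 0, with 1103 genes at an unadjusted p under 0.05. Without the arrays of 20% oxygen replicates 1, 2 and 3 the count was 24, 15 and 41, and without those labelled 0.2% oxygen replicates 1, 2 and 3 it was 1421, 12 and 898. Median centring left 2 genes higher and 0 lower (limma), in place of 66.2% higher. The excess of higher genes was absent with the replicate number as a block, 75 higher and 79 lower, and without the array labelled 0.2% oxygen replicate 1, 709 higher and 712 lower. Without that labelled replicate 2, 4 were higher and 8 lower, and without the arrays of 20% oxygen replicates 1, 2 and 3 there were 12, 5 and 21 higher and 12, 10 and 20 lower. The filter on all 12 channels gave 125, no filter 340, the authors' log ratios 448 and processed signals 527. Of the genes called at 20% oxygen, 111 higher and 66 lower genes were called the same way at 0.2% oxygen, where independence would give 8.02 and 2.82, and 0 were called opposite ways by limma. In 96.5% of the 1112 genes the sign was the same at both levels. Both levels share a dye orientation and an estimate of the spread.

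Over both oxygen levels, 9 of 18 epithelial genes fell in shETV4 cells, none rose and 9 did not pass, and adjusted over the list alone 1 rose and 11 fell (median -0.55, adjusted p = 2.03e-07, adjusted p = 0.158 with an estimated correlation). The clearest were ST14 (4.63-fold lower), CLDN7 (5.54-fold), CDH3 (3.72-fold) and EPCAM (3.35-fold). S100A9 had the smallest adjusted p (10.4-fold lower, 5.01e-05), and LCN2 was 14.5-fold and S100A14 11.5-fold lower. PRSS8, NNMT, LAD1, TGFBI, ATP2C2 and BSPRY were 9.23-fold to 11.4-fold lower. FGFBP1 was 9.43-fold, VIM 9.19-fold and REEP2 8.17-fold higher, and FEZ1, CLDN14, NTSR1, the cytokine IL33, DIO3 and EPB41L3 were 5.98-fold to 7.65-fold higher. NPTX1, not well above background in any shNTC channel, was higher too (adjusted p = 0.00241). ETV1 was 2.11-fold higher (adjusted p = 0.00619), and all 4 of its probes were higher. Of 20 NF-kB and inflammatory genes IL1B, BIRC3 and IRAK2 rose, 6 fell and 11 did not pass, also adjusted over the list alone (median -0.33, adjusted p = 0.0189, adjusted p = 0.479 with an estimated correlation). Among the falls were TNFAIP2 (2.65-fold), the chemokine CCL20 (1.79-fold), the cytokine IL6 (3.31-fold) and the prostaglandin synthase PTGS2 (3.71-fold). Of 28 cell cycle genes 4 fell, and 6 adjusted over the list alone (median -0.36, adjusted p = 1.89e-05, adjusted p = 0.479 with an estimated correlation). They were MCM4 (2.89-fold), CCNA2 (1.75-fold), the mitotic kinase AURKB (1.82-fold) and BIRC5 (1.53-fold). Of 24 respiratory chain genes ATP5F1C rose (log2 0.72) and 23 did not pass, also adjusted over the list alone (median -0.23, adjusted p = 0.0189, adjusted p = 0.479 with an estimated correlation), with COX6C at -0.42, COX5A at -0.32, NDUFB8 at -0.27 and ATP5F1A at -0.39. Of 28 ribosomal proteins RPS12 (1.60-fold) and RPL35 (1.33-fold) fell and 26 did not pass, and adjusted over the list alone 1 fell (median -0.12, adjusted p = 0.0189, adjusted p = 0.709 with an estimated correlation). RPL6 (-0.37) and RPL7 (-0.29) were next. Of 22 HIF targets in glucose metabolism PFKFB3 (2.41-fold), ENO2 (2.24-fold), GYS1 (1.72-fold) and PFKP (1.49-fold) rose, also adjusted over the list alone (median 0.29, adjusted p = 0.0724, and 0.0427 with the replicate number as a block). Of 39 other HIF targets TMEM45A (3.97-fold), TFRC (1.82-fold) and IGFBP3 (2.45-fold) rose, BHLHE41 (2.97-fold) and VEGFA (log2 -0.94) fell, also adjusted over the list alone (median 0.13, adjusted p = 0.95).

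In total 1254 genes were higher and 787 lower over both levels, 2041 of 12054. Without the array of 20% oxygen replicate 1, 2 or 3 there were 517, 529 and 721, without that labelled 0.2% oxygen replicate 2 there were 1068, and without that labelled 0.2% oxygen replicate 3 there were 4075. The filter on all 12 channels gave 724. Median centring moved the median of all genes by 0.35 and gave 202 genes higher and 51 lower, 79.8% higher in place of 61.4%. With it the medians of the cell cycle (0.08), NF-kB (0.00), respiratory (0.32) and ribosomal (0.49) lists were positive, the respiratory and ribosomal lists lost their calls (adjusted p = 0.565 each), and RPL35 turned to 0.20 (adjusted p = 0.83). The filter on all 12 channels ended the NF-kB (adjusted p = 0.202), respiratory (adjusted p = 0.051) and ribosomal (adjusted p = 0.0588) calls, and the authors' log ratios the latter ones (adjusted p = 0.115 and 0.385), the ribosomal one also lost with processed signals (adjusted p = 0.232). In fry only the epithelial list passed (adjusted p = 0.00123). Without the array labelled 0.2% oxygen replicate 3 the NF-kB list had an adjusted p of 0.0755. Without the one labelled replicate 1 the respiratory list had 0.0949 and the ribosomal list 0.115, and without replicate 2 the glucose list passed (adjusted p = 0.00322).

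**Figure D3:**
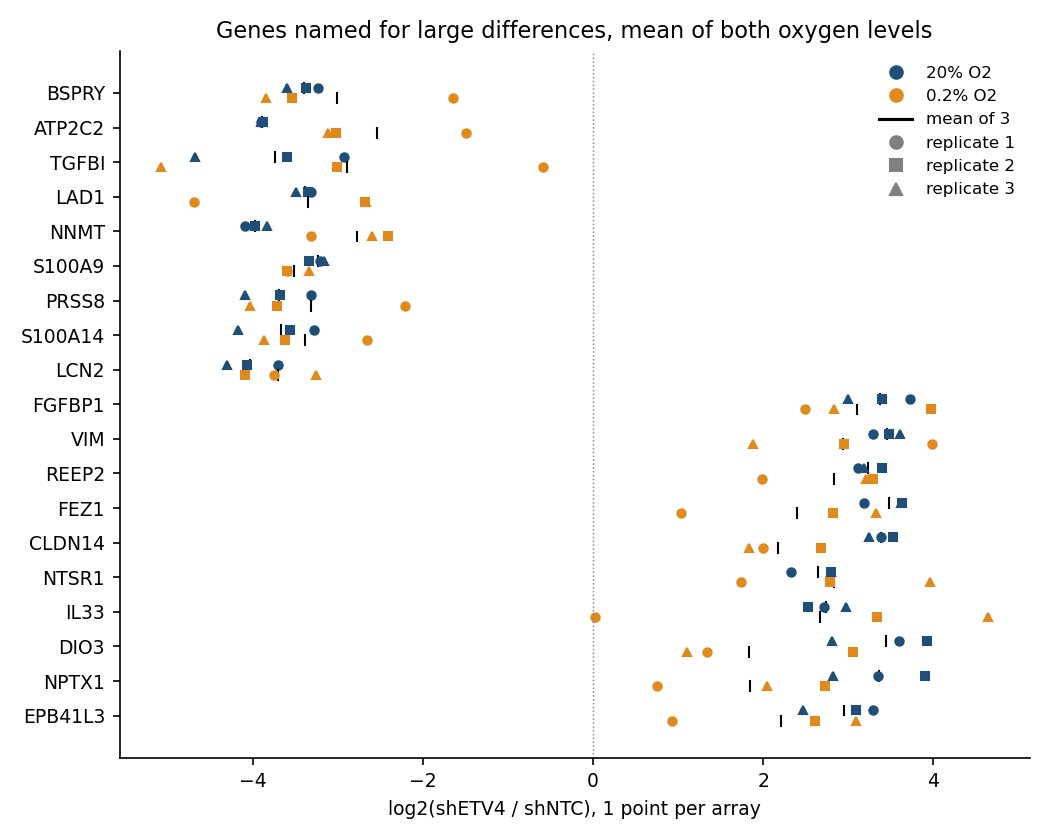
Log2 ratio of shETV4 over shNTC on each of the 6 arrays for the genes named for a large rise or fall over both oxygen levels. Each point is an array, with blue for 20% oxygen, orange for 0.2% oxygen, a marker per replicate number and bars at the mean of 3 arrays. The means over both levels run from -3.86 for LCN2 to 3.24 for FGFBP1.

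The difference of the shETV4 effect between 0.2% and 20% oxygen asked whether low oxygen altered what the knock-down did. No single gene passed. The smallest p values belonged to KCNK5, a potassium channel gene, and EPN3, with log2 differences of 2.38 and 2.01 (adjusted p = 0.0648 each). GUCY1A1 (1.60), MCF2L-AS1 (1.5) and NANOS1 (1.41) followed, and on the negative side LHFPL6 (-1.70), IDO1 (-1.19), GULP1 (-1.18), CA1 (-1.64) and SSBP2 (-1.03). The difference for ETV4 was 1.39 (adjusted p = 0.634) and for ETV1 -0.65 (adjusted p = 0.66). The limma fit called 0 of 12054 genes, with 913 at an unadjusted p under 0.05.

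Of 28 cell cycle genes none passed, and none adjusted over the list alone. Their median difference was -0.57 (adjusted p = 3.91e-06, adjusted p = 0.542 with an estimated correlation), the ratio of shETV4 over shNTC being lower at 0.2% oxygen. BUB1B (-1.10), CCNE2 (-1.39), CDK1 (-0.93) and TOP2A (-0.95) had the smallest p. Median centring moved the median of all genes by 0.58, and the median of this list was then 0.29 (adjusted p = 0.153). Of 25 interferon response genes none passed, and none adjusted over the list alone (median 0.47, adjusted p = 6.7e-05, adjusted p = 0.542 with an estimated correlation). OASL (1.25), IFIT1 (1.27), IFIT3 (0.81) and OAS1 (0.70) had the smallest p. With the replicate number as a block the epithelial (median 0.31) and unfolded protein (median 0.26) lists also passed, each at an adjusted p of 0.0427 in place of 0.0522. The HIF targets in glucose metabolism had a median of 0.22 (adjusted p = 0.132), with SLC16A3 at 0.62, GPI at 0.48, GYS1 at 0.95 and HK1 at 0.56. The other HIF targets had a median of -0.12 (adjusted p = 0.598), with WSB1 at 1.24, VLDLR at -0.86, TFRC at 0.86 and PLOD1 at 1.26. None of either list passed, adjusted over the list alone either. Without the array labelled 0.2% oxygen replicate 1 the other HIF targets had a median of -0.70 (adjusted p = 2.62e-06), and without replicate 2 the glucose list had 0.46 (adjusted p = 0.000706). The epithelial and unfolded protein lists passed without the array of 20% oxygen replicate 1 (adjusted p = 0.0168 each) and without that labelled 0.2% oxygen replicate 2 (adjusted p = 0.00823 each) or 3 (adjusted p = 0.0365 and 0.000878). The mesenchymal, ribosomal, cholesterol, ETS and RAS-ERK lists passed without some single arrays, at adjusted p from 0.0066 to 0.0473. With array 2 alone at 0.2% oxygen the cell cycle list did not pass (median -0.18, adjusted p = 0.133).

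In shNTC cells 24 of 39 other HIF targets were higher and 5 of 28 cell cycle genes lower at low oxygen, and neither list held its call with an estimated correlation. That test used only the 6 Cy5 channels, the dim one among them, and a fit to these called 6 genes. ANGPTL4, a secreted regulator of lipoprotein lipase and HIF target, was 48.5-fold higher at 0.2% oxygen (log2 5.6 ± 0.49, SE of the separate-channel fit, 3 channels per oxygen level). SLAMF9 was 34.3-fold higher. The chemokine receptor ACKR3, DEPP1, the lipid droplet gene HILPDA, ANKRD37, the vasodilator adrenomedullin (ADM), IGFBP3, DUSP1 and NDRG1 were 10.9-fold to 26.3-fold higher. The growth factor gene CSF3 was 8.04-fold lower and the protease inhibitors SERPINB4 and SERPINB3 6.99-fold and 6.31-fold lower. WDR4 was at least 5.48-fold lower, and GPATCH4, KCNK5, DDX28, SHISA3, EPN3 and ZNF239 were 4.77-fold to 5.44-fold lower. ETV4 had a log2 change of -1.23 (adjusted p = 0.118) and ETV1 of 0.07 (adjusted p = 0.896).

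Of 39 other HIF targets 24 rose in shNTC cells, none fell and 15 did not pass, and adjusted over the list alone 32 rose and 1 fell (median 1.86, adjusted p = 3.36e-26, adjusted p = 0.254 with an estimated correlation). VLDLR rose at least 5.55-fold and TMEM45A 7.75-fold. Of 22 HIF targets in glucose metabolism PFKFB3 (6.97-fold), ENO2 (5.13-fold), the glycogen branching enzyme GBE1 (3.74-fold) and PFKFB4 (4.76-fold) rose, 18 did not pass, and adjusted over the list alone 10 rose (median 0.54, adjusted p = 4.92e-08, adjusted p = 0.254 with an estimated correlation). Of 24 genes of the unfolded protein and amino acid response, 4 rose and 20 did not pass, and adjusted over the list alone 11 rose (median 0.66, adjusted p = 8.01e-06, adjusted p = 0.254 with an estimated correlation). They were SESN2 (3.09-fold), NUPR1 (2.60-fold), DDIT3 (2.49-fold) and PPP1R15A (3.22-fold). Of 28 cell cycle genes 5 fell, none rose and 23 did not pass, and adjusted over the list alone 12 fell (median -0.73, adjusted p = 1.3e-05, adjusted p = 0.254 with an estimated correlation). The mitotic kinases PLK1 (4.17-fold) and AURKB (2.55-fold), CCNA2 (2.35-fold) and MCM4 (1.99-fold) were the clearest, and CCNB1 (log2 -1.51) also fell. The other 12 lists did not pass, though the mesenchymal list did without the array labelled 0.2% oxygen replicate 2 (median 0.13, adjusted p = 0.0314). None of the 4 lists that passed did so in the fry test (adjusted p = 0.0593 each).

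In total 343 genes were higher and 435 lower at 0.2% oxygen in shNTC cells, 778 of 12054, and 278 and 314 of them changed at least 2-fold. With the replicate number as a block there were 1204. Without the arrays of 20% oxygen replicates 1 and 2 the count was 10 and 6, and without those labelled 0.2% oxygen replicates 1, 2 and 3 it was 2116, 30 and 36. Processed signals gave 187, quantile normalisation within the dye 318 and the filter on all 12 channels 219. Median scaling of intensity between arrays called 6, all higher, and a fit to the 6 Cy5 channels alone 6. The excess of lower genes turned to one of higher genes with quantile normalisation (171 higher, 147 lower), without 20% oxygen replicate 3 (473 and 381) and without the arrays labelled 0.2% oxygen replicate 2 (16 and 14) or 3 (21 and 15).

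In shETV4 cells 15 of 39 other HIF targets were higher and 11 of 28 cell cycle genes lower at low oxygen, and both lists held their call with an estimated correlation. That test used only the 6 Cy3 channels, whose fit called 731 genes, so the pools were not tested on equal terms. SLAMF9 was 36.3-fold higher (log2 5.18 ± 0.52, SE of the separate-channel fit) and ANGPTL4 32.3-fold higher. ADM, DEPP1, ACKR3, NDRG1, IGFBP3, the mTOR inhibitor DDIT4, the calcium channel ITPR1 and KCTD11 were 9.80-fold to 16.9-fold higher. Genes that were lower included the chemokine CXCL1 (5.64-fold), CDCA7 (5.43-fold), SHISA3 (5.29-fold), HIF1A, which encodes the oxygen-regulated HIF subunit (4.85-fold), FAM72A (4.53-fold) and urokinase, PLAU (4.42-fold). S100A8 was 4.37-fold, the splicing factor SRSF7 4.32-fold, cyclin CCNB1 4.03-fold and CDC20 3.93-fold lower. ETV4 had a log2 change of 0.16 (adjusted p = 0.9) and ETV1 of -0.58 (adjusted p = 0.279).

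Of 39 other HIF targets 15 rose in shETV4 cells, none fell and 24 did not pass, and adjusted over the list alone 32 rose. Their median was 1.71 (adjusted p = 2.3e-29), and the call held with an estimated correlation (adjusted p = 0.00769). CA12 rose 2.72-fold and TMEM45A 6.07-fold. Of 28 cell cycle genes 11 fell, none rose and 17 did not pass, and adjusted over the list alone 23 fell. Their median was -1.27 (adjusted p = 4.18e-21), and this call held too (adjusted p = 0.023 with an estimated correlation). BUB1B (2.82-fold), CCNA2 (2.80-fold), CCNB1 and MCM7 (3.26-fold) were the clearest. Of 22 HIF targets in glucose metabolism 7 rose and 15 did not pass, and adjusted over the list alone 15 rose (median 1.06, adjusted p = 7.78e-15, adjusted p = 0.0894 with an estimated correlation). They included PFKFB3 (5.51-fold), ENO2 (5.34-fold), PFKFB4 (8.23-fold) and GPI (2.08-fold). Of 24 genes of the unfolded protein and amino acid response 5 rose, and 14 adjusted over the list alone (median 0.99, adjusted p = 1.92e-12, adjusted p = 0.0934 with an estimated correlation). NUPR1 (3.86-fold), SESN2 (3.96-fold), TRIB3 (3.88-fold) and SHMT2 (1.76-fold) were the clearest, and ASNS (log2 2.11) also rose. Of 18 epithelial genes the mucin MUC1 rose 9.62-fold and 17 did not pass, and adjusted over the list alone 2 rose (median 0.48, adjusted p = 0.0012, adjusted p = 0.175 with an estimated correlation). PKP3 (1.04), DSP (0.98) and CLDN7 (0.97) did not pass. Median scaling between arrays ended that call (adjusted p = 0.147). The reported PEA3 targets did not pass (median 0.57, adjusted p = 0.0517), but did without the array of 20% oxygen replicate 2 (adjusted p = 0.0387) or without that labelled 0.2% oxygen replicate 1 (adjusted p = 0.0435) or 2 (adjusted p = 0.0163). They also passed with the replicate number as a block (adjusted p = 0.0475), without background correction (adjusted p = 0.0408), with processed signals (adjusted p = 0.0218), with the mean over the probes of a gene (adjusted p = 0.0186), with array 2 alone at 0.2% oxygen (adjusted p = 0.047) and in fry (adjusted p = 0.00221). The 5 lists that passed camera also passed fry (adjusted p from 3.87e-05 to 0.00316). The other 10 lists did not pass.

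In total 219 genes were higher and 185 lower at 0.2% oxygen in shETV4 cells, 404 of 12054, and 175 and 133 of them changed at least 2-fold. Without the arrays of 20% oxygen replicates 1 and 2 the count was 4 each time, and without those labelled 0.2% oxygen replicates 2 and 3 it was 71 and 26. Processed signals called 50 genes higher and 24 lower, 67.6% higher in place of 54.2%, and median scaling between arrays 9 higher and 2 lower. Quantile normalisation gave 188 higher and 208 lower, and no filter 224 and 233. A fit to the 6 Cy3 channels alone called 731, and array 2 alone at 0.2% oxygen 14.

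**Figure D4:**
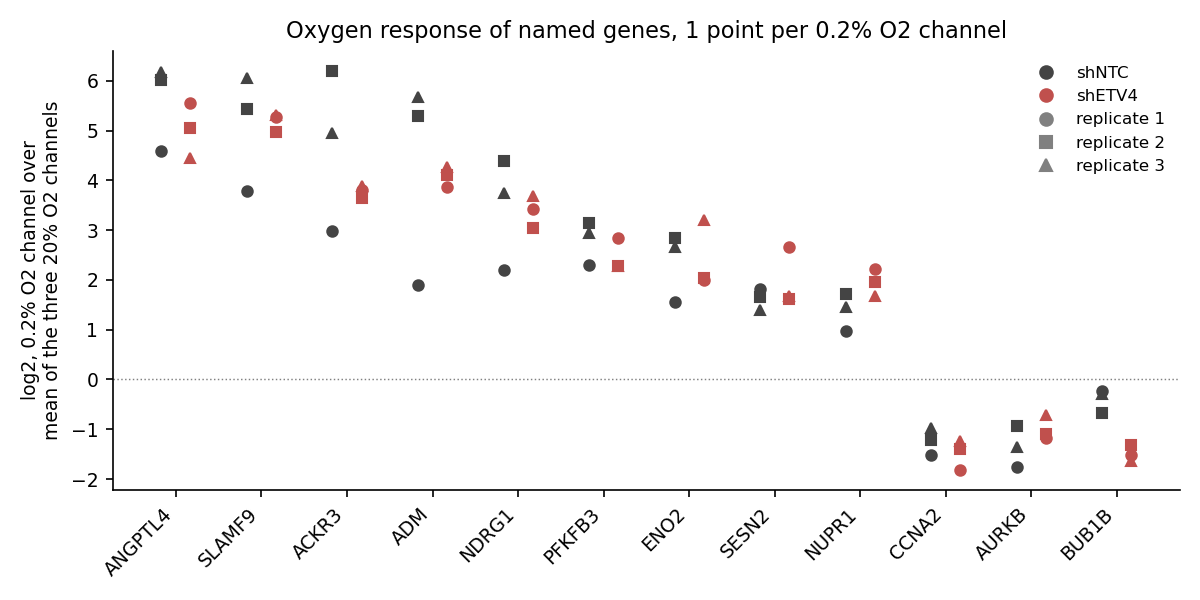
Log2 change of 12 named genes in each channel at 0.2% oxygen against the mean of the 3 channels of the same pool at 20% oxygen. Points are single channels of shNTC or shETV4 cells. ANGPTL4 and SLAMF9 lie highest, with group means of 5.6 and 5.10 in shNTC cells and 5.01 and 5.18 in shETV4 cells, and CCNA2, AURKB and BUB1B lie below 0 on average.

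Genes raised by low oxygen in shNTC cells were compared between pools in cultures not used to choose them. The choice used the shNTC response alone, and no choice on the shETV4 response was run. It favours genes that respond more in the shNTC channels, so a negative value does not by itself show a smaller response in shETV4 cells. Between 506 and 980 genes were at least 2-fold higher at 0.2% oxygen on the arrays used for choosing. The log2 ratio of shETV4 over shNTC for them changed from 20% to 0.2% oxygen by a median of 0.31, -0.56 and -0.74 in the arrays of replicate numbers 1, 2 and 3. The mean was -0.33 ± 0.57 (SD, 3 rotations, exact sign-flip p = 0.5). For genes at least 2-fold lower the mean was 0.53 ± 0.63, and for genes within 1.2-fold -0.02 ± 0.04 (exact sign-flip p = 0.5 for each). The number that went the other way includes the dim shNTC channel. With replicate number 1 left out the mean was -0.60, and with number 3 left out 0.09.

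**Figure D5:**
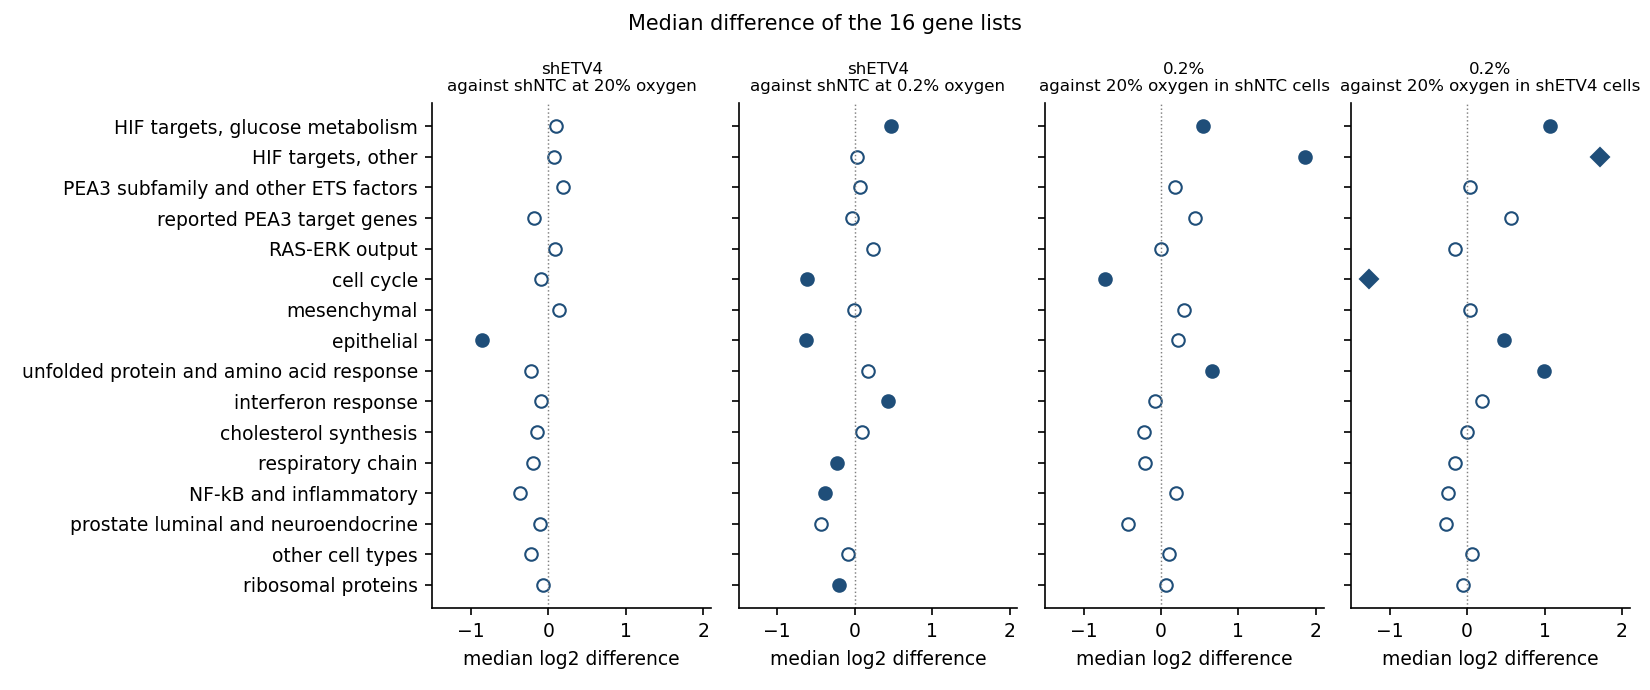
Median log2 value of the 16 gene lists in 4 comparisons, which are the effect of shETV4 at each oxygen level and the effect of low oxygen in each pool. Filled points passed camera at the preset correlation and diamonds also with an estimated one, which are the other HIF targets (1.71) and the cell cycle list (-1.27) in shETV4 cells. With median centring the medians of the cell cycle, epithelial, NF-kB, respiratory and ribosomal lists at 0.2% oxygen turned positive. For the effect of low oxygen, the test with an estimated correlation used only the channels of 1 dye.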

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

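The tests of the dim channel, of exchanged RNAs and of a signal near background were chosen after the results they address had been seen. The shETV4 effect on the cell cycle list was lower at 0.2% than at 20% oxygen by a median of -0.57, and that on the interferon list higher by 0.47, in camera tests of the difference. With an estimated correlation neither held (adjusted p = 0.542 each), nor in fry (adjusted p = 0.235 each), and with median centring the median of the cell cycle list was 0.29 (adjusted p = 0.153). For IFIT1 (1.27), BUB1B (-1.10), CCNE2 (-1.39) and GPI (0.48) all 3 arrays of one oxygen level lay on the other side of 0 from all 3 of the other. These 4 were picked by sign and not by a test, and the limma test of the difference did not pass for them (adjusted p from 0.599 to 0.631).

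The shNTC channel of the array labelled 0.2% oxygen replicate 1 was 20.5-fold dimmer than the median Cy5 channel, and its 61 HIF targets lay 0.70 above the 20% oxygen channels on the log2 scale, against 2.25 and 1.92 on the other arrays. Compression by a signal near background was argued against by the 49 targets above background, whose background-subtracted median shift was 0.55 here and 2.33 and 2.20 there. Cy3 light read in the Cy5 channel was argued against by a rank correlation of 0.803 with the Cy3 channel, below 0.955 with shNTC cells at 20% oxygen replicate 1. That channel gave the highest correlation of the 11 others, and shNTC RNA of 20% oxygen may have been in the dim channel, but cannot be told apart from a culture with a weak response, since the shift of 0.55 lies outside the range of the 20% oxygen channels (-0.11 to 0.05). Over 2058 probes at least 2-fold apart between oxygen levels, the channel's median position was 0.979, where 1 is the level of the shNTC channels at 20% oxygen and 0 that of the other shNTC channels at 0.2%. The array lay at slide position 1_2, between 20% oxygen replicates 1 (1_1) and 2 (1_3). Their shNTC channels gave its highest correlations, 0.955 and 0.940, and correlated at 0.975 with each other. Replicate 3 at 20% oxygen (2_2) gave 0.815, and the shNTC channels labelled 0.2% oxygen replicates 2 and 3 gave 0.819 and 0.784. The shNTC channel of 20% oxygen replicate 3 correlated at 0.811 and 0.834 with 20% oxygen replicates 1 and 2. With the shNTC channel labelled 0.2% oxygen replicate 3 it correlated at 0.857. Rank correlation therefore did not sort the shNTC channels by oxygen level. A link with slide position was not tested. Scaled to bright probes, ETV4 was 0.40 in the dim channel, 0.43, 0.24 and 0.06 at 20% oxygen and 0.08 and 0.05 in the other shNTC channels.

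On the array labelled 0.2% oxygen replicate 3 the ETV4 log2 ratio was -0.11. With the channels as labelled, a lost knock-down was tested on the 818 genes passing and over 2-fold different on the 20% oxygen arrays alone. On this array their log2 ratios had the same sign as at 20% oxygen in 81.1%. The slope was 0.67 ± 0.02 (SE over genes of 1 array), against 0.48 and 0.79 on the arrays labelled replicates 1 and 2. Over all 18580 kept probes this array's log2 ratios correlated at 0.10, 0.14 and 0.31 with the arrays at 20% oxygen. A slope this high had been set beforehand as evidence against a lost knock-down. A probe dye effect or a lasting difference between pools would also give it, so a lost knock-down is not excluded. In the shETV4 channel both ETV4 spots were above background with 90.5 units, which argued against a signal too near background for that channel only. The shNTC channel read 63 units there, against 862 and 838 at 20% oxygen replicates 1 and 2. Whether a control signal this low can show a fall was not tested. The shETV4 RNAs of replicates 1 and 3 at 0.2% oxygen may have been exchanged, since deviations from the group means correlated at 0.52 and 0.60 with the crossed numbers at 20% oxygen and at -0.53 and -0.54 with their own. Number 2 did not pair with itself either (-0.09). Number 2 at 0.2% oxygen correlated at 0.32 with number 3 at 20% oxygen, and number 3 at 0.2% oxygen at 0.32 with number 2. Deviations from a shared mean depend on each other, so these correlations cannot settle an exchange. Crossing the shETV4 RNAs of replicates 1 and 3 would give ETV4 ratios of -0.39 and -0.56 with slopes of 0.36 and 0.79. The first rests on the dim shNTC channel and the second on a shETV4 channel with no ETV4 spot above background. A culture that regained ETV4 while its other differences persisted was not tested.

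The genes that differed between shETV4 and shNTC cells were all measured in 1 dye orientation. A dye bias of single probes as the whole cause was argued against by 482 other probes of 431 called genes. Their log2 ratios followed those of the first probe with a slope of 0.55 ± 0.02 (SE over probes, not cultures) and the same sign in 91.3%. With the channels as labelled, that the ETV4 level sets their size was argued against by the array labelled 0.2% oxygen replicate 3. There both ETV4 spots were above background in both channels. The same RNAs gave an ETV4 ratio of -0.11 and a slope of 0.67 ± 0.02 (SE over genes of 1 array). The ETV4 signals there were low, at 63 and 90.5 units. The mean ETV4 ratio at 0.2% oxygen was -0.73, and -2.15 with processed signals, so the ratio of -0.11 is itself uncertain. In the crossed arrangement the smallest ETV4 ratio, -0.39, had the smallest slope, 0.36 (72.2% with the same sign), so the argument holds only as labelled, and ETV4 in the shETV4 channels of the other arrays at 0.2% oxygen was too near background to rank them. An effect of the hairpin or of the pool that does not pass through ETV4 was not tested, since the labels give 1 shETV4 group.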

How the results depend on the processing

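Keeping only array 2 at 0.2% oxygen, and leaving out arrays for the list tests, the held-out measure and the ETV4 ratio, were chosen after the data were seen. Of 425 repeats of list calls 355 stayed on the same side of the threshold in the same direction, 69 lost the call and 1 reversed. Of 3915 repeats for named genes 3074 did so, 729 lost the call, 83 gained one, 1 reversed and 28 without a call changed sign. The cause of the changes below was not tested, except that fewer arrays leave fewer degrees of freedom and the filter tests fewer genes. The spread of 6 arrays and signal near background limit what can be called.

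For shETV4 against shNTC at 20% oxygen (1112 genes), processed signals gave 588, the filter on all 12 channels 238, median centring 15, the authors' log ratios 555, only the 3 arrays 5101 and array 2 alone also 5101, since a lone array adds no spread. Leaving out 1 array gave 32 to 3188. At 0.2% oxygen (222) processed signals gave 527, no filter 340, all 12 channels 125, median centring 2, the authors' log ratios 448, only the 3 arrays 0 (limma, 1103 at an unadjusted p under 0.05) and array 2 alone 2594, and leaving out 1 array 12 to 1421. Over both levels (2041) all 12 channels gave 724, median centring 253 and array 2 alone 4949, and leaving out 1 array 517 to 4075. For the difference (0) no filter gave 2 and array 2 alone 652, and leaving out 1 array 0 to 2, with 913 at an unadjusted p under 0.05 in limma before.

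For oxygen in shNTC cells (778) processed signals gave 187, all 12 channels 219, the replicate block 1204, quantile normalisation within the dye 318, median scaling 6 and only the 6 channels 6, and leaving out 1 array 6 to 2116. In shETV4 cells (404) processed signals gave 74, the replicate block 715, median scaling 11, only the 6 channels 731 and array 2 alone 14, and leaving out 1 array 4 to 516. The numbers did not pair the shETV4 channels. The block changed no other total by over 1.5 times, but at 0.2% oxygen shETV4 cells then had 75 genes higher and 79 lower, in place of 147 and 75.

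The 24 list calls became 2 with an estimated correlation, 10 with fry and 28 with the replicate block, and 23 to 31 when 1 array was left out. The ETV4 ratio at 20% oxygen was -2.06 with median centring (adjusted p = 0.166), -3.1 with processed signals (adjusted p = 0.033), -3.16 with the authors' log ratios (adjusted p = 0.029) and -2.67 to -1.72 when 1 array was left out. At 0.2% oxygen it was -2.15 (adjusted p = 0.1) and -2.19 (adjusted p = 0.097) in these, and -1.03 to -0.48 with 1 array left out. The held-out measure was -0.60 to 0.09 with 1 number left out. The glucose list at 0.2% oxygen reversed with array 2 alone (median -0.14, adjusted p = 0.414), and RPL35 over both levels with median centring (0.20, adjusted p = 0.83).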

Other observations

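The gene families here were chosen after their values had been seen, as were the tests of their change and the test of a smaller oxygen response. The p values of the families do not account for that choice, so they describe the families and are no independent evidence. Over both oxygen levels, 9 of 11 clustered protocadherin genes, which encode neuronal cell adhesion proteins, were higher in shETV4 cells and none was lower (median log2 ratio 0.91, camera adjusted p = 1.49e-05 over 7 families, adjusted p = 0.293 with an estimated correlation). Among them were PCDHB11 (1.29), PCDHB14 (1.28) and PCDHA11 (1.17). All 3 serum amyloid A genes were lower, SAA1 at -2.47, SAA2 at -2.36 and SAA4 at -1.36 (adjusted p = 1.24e-05, adjusted p = 0.0599 with an estimated correlation). All 3 aldo-keto reductase genes of the AKR1C group were higher, AKR1C1 at 2.38, AKR1C3 at 2.21 and AKR1C4 at 0.38 (adjusted p = 0.000597, adjusted p = 0.0881 with an estimated correlation). Of 363 zinc finger genes named ZNF, 73 were higher and 6 lower (median 0.20, adjusted p = 9.66e-05, adjusted p = 0.293 with an estimated correlation). Relative to the median of all genes, which median centring moved by 0.35, these 4 families kept their direction in every setting run. Members of the first 3 families are close in sequence, and how far probes read more than 1 of them was not tested. Of 22 collagen genes 7 were higher and 2 lower (adjusted p = 0.363), and of 6 genes of the HOXB cluster 1 was higher and 3 lower (median -0.50, adjusted p = 0.0166, adjusted p = 0.293 with an estimated correlation).

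Of 25 genes of ribosome assembly named RRP, NOP or UTP, 11 were lower and none higher at 0.2% oxygen in shNTC cells (median -1.06, adjusted p = 6.09e-10, adjusted p = 0.232 with an estimated correlation). In shETV4 cells UTP18 was lower and none was higher (median -0.76, adjusted p = 1.78e-05, adjusted p = 0.0327 with an estimated correlation). Examples in shNTC cells were RRP15 (-2.24), NOP2 (-1.87) and RRP12 (-1.79). Relative to all genes the median was negative in every setting run. Of 3762 kept probes without a symbol, 282 differed between shETV4 and shNTC cells over both levels. This count was adjusted over all 18580 kept probes, of which 2384 differed.

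A smaller oxygen response in shETV4 than in shNTC cells was considered as a hypothesis. The held-out median difference was -0.33 on average, but negative in 2 of 3 rotations, and 3 rotations cannot give a p under 0.25. The genes were also chosen on the shNTC response alone, which favours a negative value. The hypothesis may or may not hold.

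Other sign patterns or splits of the arrays were compared with the real ones by their number of called genes in limma. Over both oxygen levels, 1 of 32 sign patterns, the real one, called as many as 2041, and the highest other called 823. That other pattern turned only the array labelled 0.2% oxygen replicate 3, and the remaining patterns called 0. The log ratios pair by replicate number, and only 4 of the 32 patterns keep the pairs whole. Here and for the other comparisons the splits are too few for a share under 0.05. The real count and the highest other were 1112 and 0 at 20% oxygen and 222 and 3 at 0.2% oxygen, over 4 sign patterns each. In the oxygen comparison they were 778 and 2 in shNTC cells and 404 and 0 in shETV4 cells, over 10 splits each. The 3 other splits that part all 3 pairs, where the numbers pair the shNTC channels, each called 0. For the difference all 10 splits called 0. The real one had 913 genes at an unadjusted p under 0.05, and this count was not made for the other splits.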
